A study of Homo sapiens with 34 samples.

How the data were processed

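RNA of established colon cancer cell lines was measured on 34 arrays with 2 dyes. Per the labels, each array carried a universal mRNA reference in Cy3 and a cell line in Cy5. The titles put 2 arrays in HCT116, 1 array in HCT116+Ch2, 1 array in HCT116+Ch3 and 30 arrays in other colon cancer lines. HCT116 is a colon carcinoma line, and the suffixes are read here as an added chromosome 2 or chromosome 3. The image addresses in the labels put the arrays in 4 imaging batches, called batches 1 to 4, with 5, 13, 13 and 3 arrays.

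The deposited values are in 2 tables, 1 per array design, called sets A and B here, with signed log ratios taken as log2. The base is not given in the sources used here. It is taken as 2 because the lowest values lie beyond the natural log of a 16-bit scanner's range. The direction is taken as line over reference from the channel labels, since the deposited tables do not state it. So the base of the scale stays unknown, while the medians show that the arrays were not centred on 0. How the authors normalized spots, subtracted background and filtered values is likewise not given in the sources used here. Set A holds 18 arrays and 43008 probes, and set B holds 16 arrays and 41568 probes. The direction was checked on gene lists fixed beforehand. Taken as line over reference, 16 of 16 mesenchymal, 14 of 16 haematopoietic and 11 of 13 hepatocyte genes were called lower and none higher, and 3 of 17 epithelial genes were called higher and none lower. With the sign turned, these epithelial cancer lines would exceed the reference in all but 4 of the connective tissue, blood and liver genes. The lowest correlation between 2 arrays over genes was 0.223 in set A and 0.200 in set B.

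The medians of the deposited arrays lay below 0. In set A the deposited log2 median was -0.86 in SW-1116, -0.79 in LS-180 and LS-174T, -0.76 in SW-480, -0.71 in NCI-H508, -0.67 in CACO-2, -0.65 in HCT116, -0.52 in SW-837, -0.47 in RKO, -0.45 in SW48, -0.41 in HCT15, -0.40 in SW620, -0.39 in SK-CO-1, -0.38 in DLD-1, -0.35 in HT-29, -0.31 in LOVO, -0.24 in SW-403 and -0.12 in NCI-H747. In set B it was -0.91 in SNUC2B, -0.83 in HCA7, -0.80 in LIM1215, -0.78 in LIM2412, -0.77 in GP5D, -0.54 in HCT116+Ch3, -0.52 in HCT 116, -0.51 in HCT116+Ch2, -0.32 in LS411, -0.29 in T84, -0.27 in SW1417, -0.24 in COLO320, -0.23 in COLO205, GP2D and COLO741, and -0.22 in SW948. Between 77.1% and 99.8% of the probes of a table had a value on an array. No spot intensities were used here, so signal over background is unknown. The number of arrays limits the precision.

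Each array was centred on its median. Probes with a value on at least 80% of the arrays of their table were kept. In set A, 21725 probes had 1 gene symbol, 814 had several and 20469 had none here. The numbers in set B were 21341, 814 and 19413. Only probes with 1 symbol were used, with symbols updated through their gene identifiers, and the probes of a gene were averaged. The probes of CDX2 did not all vary alike. Where probes of another named gene disagreed, this is said beside it. In sets A and B together, 11704 genes were measured in enough lines to be tested. No column of values was left unused.

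The tables are separate array designs that were normalized apart, so tests were run within a table. A gene was called higher or lower than the reference only if limma gave an adjusted p under 0.05 with the same sign in both sets. Known sister lines of 1 donor were averaged first, which is background knowledge and not a label. These are the 4 pairs LS-180 and LS-174T, DLD-1 and HCT15, SW-480 and SW620, and GP2D and GP5D. This left 15 donors in set A and 13 in set B, with HCT116 in each, and 28 values from 27 distinct donors in the correlations. The derivatives HCT116+Ch2 and HCT116+Ch3 entered no test. Within a set there was 1 array per line, so the spread holds differences between lines and between arrays. The reference is 1 RNA with no spread of its own, and a ratio gives a level relative to that pool and to the array median.

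limma 3.58.1 in R 4.3.3 was fitted with an intercept only for the comparison with the reference, and with the log2 ratio of CDX2 or VIM as a continuous covariate for genes that vary with them, with Benjamini-Hochberg adjustment. A gene is called supported when it passed in 1 table and had an unadjusted p under 0.05 with the same sign in the other. Lists were tested with camera at a preset correlation between genes of 0.01, and again with an estimated correlation. The 16 lists were mismatch repair, mitotic checkpoint and spindle, cell cycle, epithelial adhesion and keratins, absorptive enterocyte, secretory and goblet, mesenchymal, melanocyte, neuroendocrine, haematopoietic, hepatocyte, Wnt targets, p53 targets, antigen presentation, interferon response and coding microsatellite mutation targets. They, 17 gene pairs, the tests and the alternatives were fixed before the data were examined. A planned mismatch repair covariate and 6 of the pairs were not analysed here.

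Correlations over lines used values centred within each table and 100000 permutations of lines within the table, two-sided, so that 1e-05 is the smallest p they can give. Lines were taken to fall into clusters where 1 gap held over 0.4 of the range. Variation between lines is the SD over the donors of a set. For each list the mean correlation of its members was set against 10000 random lists of the same size matched on SD, where 1e-04 is the smallest p. For single arrays, a list or chromosome median was given its percentile among 10000 random lists matched on level. Chromosomes and gene order came from a RefSeq gene table, which was used for names and neighbours only. Python 3.11.15 with numpy 2.4.6, scipy 1.17.1 and pandas 2.3.3 ran the correlations.

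Genes were named by a rule. From the comparison with the reference these are the 10 highest and 10 lowest called genes and up to 4 members of each list. For each derivative of HCT116 they come from the genes with more than 1 probe whose probes all differed in the same direction. Of these genes, the 12 of largest difference that also differed by at least 1 from the other derivative are named. Genes with 1 probe, or with probes that disagreed in direction, are not among them, whatever the size of their difference. Supported genes of the covariates, the 25 most variable genes and 3 per list complete the rule. Members of a list of 5 or fewer calls that fall outside it were chosen after their values were seen.

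The steps were tested on simulated data. Each gene was drawn independently from a normal distribution with its own SD. The simulated data held no correlation between genes, no image runs and no outlying lines. The false calls below therefore give no error rate for the real arrays. With 100 of 11704 genes shifted by 1 or by 2, the comparison with the reference recovered 66% and 95%, with 0 false calls. With slopes of 0.5 or 1 added for 100 of 11703 genes, the CDX2 fit recovered 21% and 83% and the VIM fit 80% and 97%. Of 200 unrelated pairs, 4.5% had a permutation p under 0.05, and all 100 pairs made with r of 0.8 had one.

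The alternatives were the deposited values without centring, scaling to equal spread, quantile normalization, the most complete probe of a gene, other limits on missing values, imaging batch as a block, each line on its own, array weights, robust empirical Bayes, leaving out COLO741 and COLO320, and leaving out each line in turn. COLO741 and COLO320 were chosen for this beforehand from background knowledge. Leaving out the second run of images in batch 3, removing the mean of each image run, leaving out SW-480, SW620, COLO741 and COLO320, and the deposited median as a covariate were added after seeing the data. Relations between lists over lines, these relations without 1 of the values of HCT116, the list tests and orders of VIM values without COLO741 or COLO320, and the 19 melanocytic genes outside the fixed list, were also added then. No classes of lines by genetic instability were compared, because the labels give none.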

Results

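The series concerns genetic instability in colon cancer, and its 34 arrays measured transcript levels of colon cancer cell lines against a common reference RNA. Set A held 18 arrays in imaging batches 1 and 2, and set B held 16 arrays in batches 3 and 4. HCT116 was measured in each set. The derivatives HCT116+Ch3 and HCT116+Ch2 were measured once each, in set B. The other 30 arrays each held 1 named line, and the labels put these lines in no further groups. All values are log2 ratios of a line over the reference after centring each array, so 0 is the array median.

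The lines as a panel had low levels of connective tissue, blood and liver genes. The matricellular gene POSTN was lowest by the mean of the 2 sets, at -7.57 ± 1.67 (SD, n = 14 donors) in set A and -5.20 ± 0.43 (n = 13) in set B, below 0 in every donor measured. SRGN, the core protein of haematopoietic granules, averaged -7.23 ± 0.94 (n = 15) and -5.35 ± 0.71 (n = 13). The liver genes APOB (-6.69 and -5.53) and AFP (-6.47 and -5.50) and the plasma cell gene JCHAIN (-6.46 and -4.68) lay below 0 in every donor measured too. At the other end was H4C3, a histone H4 gene, at 3.75 ± 0.77 (n = 15) and 3.39 ± 0.69 (n = 13), above 0 in every line. RNF43, a ubiquitin ligase that dampens Wnt receptors, averaged 2.23 ± 1.71 and 2.30 ± 1.48, and SOX9, a transcription factor of crypt cells, 2.33 ± 1.93 and 1.84 ± 1.95. The colonic homeobox gene HOXB5 averaged 2.88 ± 2.28 and 1.84 ± 1.00.

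The 10 highest called genes were completed by SH3BGRL2, LIPH, UGT8, GPRC5A, EXPH5 and ARHGAP32, with set means between 1.31 and 2.87. The 10 lowest were completed by SPP1, IL13RA2, LCP1, MAL and SPARC, with set means between -6.86 and -3.99. limma called 1801 genes higher and 2167 lower than the reference in both sets, so 45.4% of the calls were higher. This split depended on the zero point. With the values as deposited the median of all genes lay at -0.55 in set A and -0.54 in set B, and 286 genes were called higher and 4678 lower, with 5.76% higher. GPRC5A was then no longer called, and neither it nor SOX9 was called without the second run of images in batch 3, an alternative chosen after seeing the data. That alternative gave 991 genes higher and 1777 lower, with 35.8% higher. Restricting the test to probes present on every array gave 1818 higher and 886 lower, with 67.2% higher.

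All 16 measured mesenchymal genes were lower than the reference, and none was higher. The intermediate filament gene VIM averaged -5.93 ± 1.72 (n = 15) and -4.19 ± 1.88 (n = 13), and N-cadherin, CDH2, -5.95 ± 1.31 (n = 13) and -4.04 ± 1.38 (n = 13). Of 16 haematopoietic genes 14 were lower, among them CD52 (-4.54 and -4.01), the T cell receptor subunit CD3D (-4.18 and -4.18) and the tetraspanin CD53 (-4.81 and -2.90). Of 13 hepatocyte genes 11 were lower, among them transferrin, TF (-5.27 and -4.29), and the apolipoprotein genes APOA2 (-5.18 and -3.83) and APOA1 (-3.77 and -4.70). The counts adjusted over the list alone were the same 16, 14 and 11. With camera and an estimated correlation the mesenchymal list had adjusted p of 0.00272 in set A and 0.0231 in set B, the haematopoietic list 0.00272 and 0.0214, and the hepatocyte list 0.0627 and 0.00689.

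Neuroendocrine genes were lower for 5 of 11 members, including the adhesion gene NCAM1 (-2.98 and -2.23) and the granins SCG2 (-2.60 and -1.79), SCG3 (-2.23 and -1.87) and CHGB (-1.66 and -1.61), and STMN2 (-1.50 and -0.58). SCG2 was no longer called without T84, COLO205, SW948 or the GP2D pair, and SCG3 and CHGB without the second run of images. Melanocyte genes were lower for 4 of 11 members, the pigment enzyme TYRP1 (-3.05 and -2.96), SOX10 (-2.92 and -2.41), the transporter SLC45A2 (-2.01 and -1.68) and S100B (-1.88 and -1.56). Both counts adjusted over the list alone were unchanged at 5 and 4. In set B these 4 melanocyte genes were above 0 in COLO741 and in no other donor. Camera at the preset correlation gave the neuroendocrine list adjusted p of 0.00616 and 0.155 and the melanocyte list 9.75e-07 and 0.182. With an estimated correlation the adjusted p was 0.029 and 0.2 for the first and 0.00272 and 0.975 for the second.

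Of 12 interferon response genes 3 were lower, the virus-tethering gene BST2 (-1.84 ± 1.56, n = 14, and -2.28 ± 1.37, n = 13), the GTPase GBP1 (-1.59 ± 1.51 and -1.40 ± 2.01) and ISG15 (-1.26 ± 0.92 and -0.84 ± 1.09). IFI27 went the other way without passing the test in both sets, at 1.01 ± 2.88 and 1.72 ± 2.68. Of 10 antigen presentation genes only the class II gene HLA-DPA1 was called, at -1.13 ± 1.16 and -1.01 ± 0.49. Among 14 absorptive enterocyte genes carbonic anhydrase 2, CA2, was lower at -3.69 ± 1.77 and -3.46 ± 1.65, as was the brush border peptidase ANPEP at -2.33 ± 1.83 and -0.93 ± 0.70. Of 15 secretory and goblet genes the trefoil factors TFF1 (-3.33 and -3.04) and TFF3 (-1.53 and -1.21) were lower, and the glycosyltransferase GALNT12 (1.47 and 1.34) and KLF4 (0.89 and 0.78) were higher. The counts adjusted over the list alone were 3, 1 and 2 lower for the first 3 of these lists, and 2 higher and 2 lower for the last. None of these 4 lists passed camera in either set. GBP1 was no longer called without HCT 116, and GALNT12 was not called on the deposited scale or without the second run of images.

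Epithelial adhesion and keratin genes were higher for 3 of 17 members, the vesicle GTPase RAB25 (1.30 ± 2.12, n = 15, and 1.57 ± 1.40, n = 12), KRT18 (1.31 ± 1.04 and 1.00 ± 1.20) and CLDN3 (1.14 ± 1.07 and 0.61 ± 0.53), and lower for none. The other 14, among them EPCAM (1.44 ± 1.74 and 0.83 ± 2.42) and E-cadherin, CDH1 (1.47 ± 2.05 and 0.79 ± 2.06), did not pass in both sets. The camera adjusted p of the list was 0.00167 in set A and 0.178 in set B, and with an estimated correlation the adjusted p was 0.58 and 0.975. Of 14 Wnt target genes RNF43, SOX9 and MYC (0.85 and 0.69) were higher, and LEF1 (-2.35 and -1.92) and FGF18 (-1.25 and -1.75) were lower. Of 17 p53 targets SERPINB5 (2.12 ± 2.97 and 1.12 ± 1.64) and the death receptor gene TNFRSF10B (0.70 and 0.44) were higher, and FAS (-0.49 and -1.17) and MDM2 (-0.59 and -0.99) were lower. Adjusted over the list alone these counts were 3 higher for the epithelial list, 2 higher and 2 lower for the Wnt targets, and 2 higher and 2 lower for the p53 targets. RAB25, KRT18 and SERPINB5 lost their calls on the deposited scale and without the second run of images. RAB25 also lost it without NCI-H508, the LS-180 pair, SW-403, HCT116, SW-1116, SK-CO-1, NCI-H747 or CACO-2, SERPINB5 without T84, COLO205, LIM2412, SNUC2B or SW1417, and FAS without HT-29, SW48, NCI-H747 or CACO-2.

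Among 16 mismatch repair genes 5 were higher and 2 lower. The clamp loader genes RFC5 (0.89 ± 0.45 and 0.82 ± 0.59), RFC1 (0.69 and 0.55), RFC3 (0.74 and 0.33) and RFC4 (0.53 and 0.51) and the MutL homologue MLH3 (0.86 ± 0.85 and 0.76 ± 0.56) were higher, and the polymerase POLD1 (-0.79 ± 0.94 and -1.06 ± 0.68) and PMS1 (-0.48 and -0.55) were lower. Of 20 cell cycle genes MKI67 (0.93 ± 0.84 and 0.47 ± 0.56) and RRM1 (0.76 ± 0.80 and 0.58 ± 0.60) were higher. Of 17 mitotic checkpoint and spindle genes the kinetochore gene ZW10 (0.82 ± 0.51 and 0.60 ± 0.53) was higher and MAD1L1 lower, at -1.25 ± 0.69 in set A and -1.12 as the mean of the 2 sets. Of 16 genes known for coding microsatellite mutations TCF7L2 (1.36 ± 0.70 and 1.78 ± 0.76) and the activin receptor gene ACVR2A (0.68 ± 0.51 and 0.55 ± 0.38) were higher. Adjusted over the list alone the counts were 5 higher and 2 lower for mismatch repair, 0 for cell cycle, 1 and 1 for the mitotic list and 2 higher for the microsatellite list. None of these lists, nor the Wnt and p53 targets, passed camera. On the deposited scale RFC5, MLH3, MKI67, RRM1, ZW10 and ACVR2A lost their calls, and MKI67 lost it without LIM2412 or without HCT 116. MKI67, RRM1, ZW10 and ACVR2A also lost their calls without the second run of images.

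**Figure D1:**
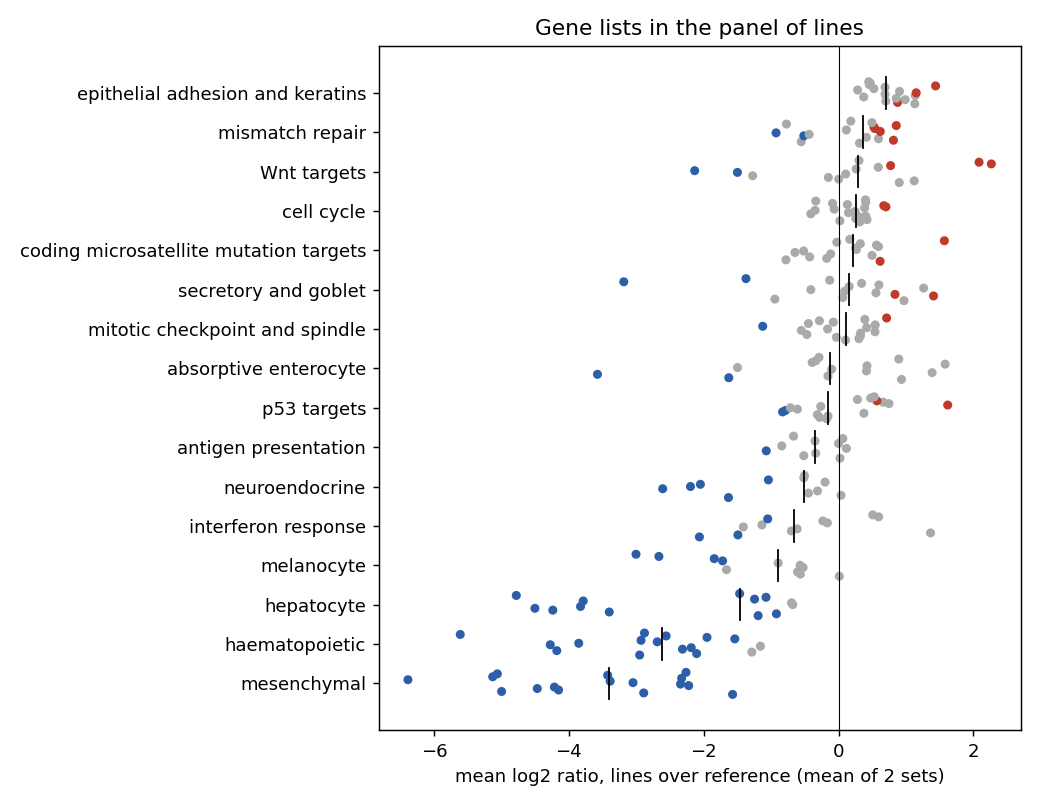
Mean log2 ratio of lines over reference for each measured member of the 16 gene lists, averaged over the 2 sets, with a black bar at the list median. Red points were called higher and blue points lower in both sets, and grey points were not called. All 16 mesenchymal points are blue.

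The titles of 2 arrays name HCT116 with an added chromosome, and the question is how these derivatives differ from HCT116. In HCT116+Ch3 the 698 chromosome 3 genes were higher as a set, with a median difference from HCT 116 of 0.31 and 72.8% of genes above 0, above all 10000 random lists. The chromosome 2 genes of the same array had a median of 0.02. In HCT116+Ch2 the 807 chromosome 2 genes had a median of 0.13, with 60% above 0, again above all random lists, and the chromosome 3 genes one of -0.06. An added copy beside 2 would give 0.58. There was 1 array of each, so these differences have no replicate check and compare arrays, not conditions. Chromosome 3 was not alone in this. HCT116+Ch3 also had raised medians on chromosomes 19 (0.20) and 22 (0.21), above all random lists as well, and on 16 (0.13) and 17 (0.09), at percentiles 99.88 and 98.6. It had low medians on chromosomes 4 (-0.09), 13 (-0.09), 14 (-0.04), 5 (-0.01) and 1 (0.01), at percentiles 0, 0.01, 0.185, 1.23 and 2.34 of random lists. In HCT116+Ch2 chromosome 9 had a median of -0.09, at percentile 1.14.

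The gains did not cover the chromosomes evenly. Over 5 consecutive blocks of chromosome 3 genes the median difference was 0.38 from CHL1 to HHATL, 0.42 from HIGD1A to SELENOK, 0.05 from CACNA2D3 to WDR5B, 0.36 from KPNA1 to MLF1 and 0.29 from GFM1 to LMLN. In 20 blocks the gap lay from TAFA4 to TOMM70 (-0.05) and from LNP1 to NAA50 (-0.14). Along chromosome 2 in HCT116+Ch2 the median was 0.32 from FAM110C to SRBD1 and 0.32 from PRKCE to SMYD1. It was 0.04 from FABP1 to LYPD6B, 0.02 from LYPD6 to CYP20A1 and -0.11 from RAPH1 to FAM240C.

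**Figure D2:**
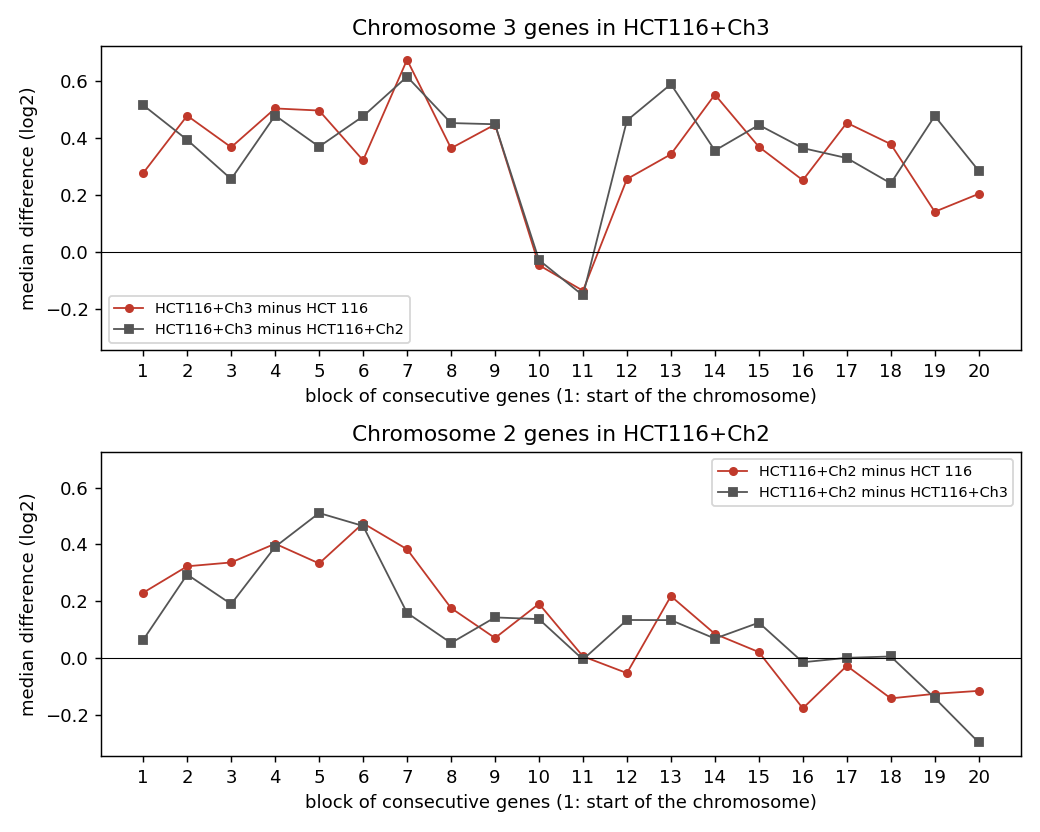
Median log2 difference of consecutive blocks of genes along chromosome 3 in HCT116+Ch3 and along chromosome 2 in HCT116+Ch2, in 20 blocks each, against HCT 116 (red) and against the other derivative (grey), with 1 array each and no error bars. Blocks 10 and 11 of chromosome 3 lie below 0 in both comparisons.

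Among single genes whose several probes agreed in direction, DCLK1, a kinase that marks tuft cells, was 5.87 higher in HCT116+Ch3 than in HCT 116. The semaphorin SEMA3A was 3.00 higher, FAM131B 2.85, SUSD2 2.81 and the chromosome 3 gene CAND2 2.56. The prolactin-induced gene PIP fell by 2.88 and PCK1, an enzyme of glucose synthesis, fell by 3.70. SRD5A2, ZSCAN12, FGL2, C3AR1 and CFB complete the 12 genes, with differences of 4.05, -4.30, -3.05, -2.91 and -2.85, but their probes disagreed in size, with a smallest difference of 1.73, 0.41, 0.77, 0.03 and 0.54 in the same directions. In HCT116+Ch2 the nuclear corepressor gene NRIP1 was 3.35 higher and COL21A1 3.33. The repair nuclease gene FAN1 fell by 3.08, the somatostatin receptor SSTR1 fell by 3.34 and CYP4B1 fell by 3.23. HCLS1 (-3.80), KAZN (-2.83), SPON1 (-2.62), the chromosome 2 transcript C2orf74-DT (2.58), PRG2 (-2.53), NBEA (-2.40) and FAIM2 (-2.40) complete the 12. For 8 of these genes too, the difference was over 1.5 times that of the probe that differed least. These smallest differences were 1.39 for HCLS1, 0.69 for SPON1, 1.24 for NBEA, 0.75 for FAIM2, 0.83 for PRG2, 1.20 for COL21A1, 2.11 for SSTR1 and 1.59 for C2orf74-DT. The same held for PCK1 in HCT116+Ch3, with 2.17. The probes of KAZN and NRIP1 were also uneven in size, with smallest differences of 2.036 and 2.335. DCLK1 differed by at least 4.95 with each of its probes. Against the other derivative some differences were smaller by over 1.5 times. They were 2.52 for DCLK1, 1.47 for SRD5A2 and -1.55 for PIP in HCT116+Ch3, and 1.92 for NRIP1, 1.49 for COL21A1, -1.62 for SPON1 and -1.31 for NBEA in HCT116+Ch2.

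Gene lists differed as well, again without replicates. The random lists were matched on level and not on the correlation between members. Lists whose members move together, such as cell cycle genes, therefore reach extreme percentiles more easily. The percentiles were not adjusted for the number of lists and comparisons. In HCT116+Ch2 the 16 absorptive enterocyte genes had a median difference of 0.66, at the 99.6th percentile of random lists, and the 10 antigen presentation genes one of -0.65, at the 0.315th. The cell cycle genes had a median of 0.27 in HCT116+Ch2 and 0.28 in HCT116+Ch3, at percentiles 99.95 and 98.98. These values share the 1 HCT 116 array, so they are not independent. In HCT116+Ch2 the mitotic genes had a median of 0.24 and the mismatch repair genes one of 0.26, at percentiles 99.03 and 98.96. The 17 p53 targets had a median of 0.18 in HCT116+Ch3 and -0.31 in HCT116+Ch2, at percentiles 85.1 and 2.91. Between the derivatives they were 0.71 higher in HCT116+Ch3, at the 99.99th percentile, and the epithelial genes 0.39 higher, at the 98.6th. The other lists named here lay within the random range between the derivatives, with medians of -0.26 for absorptive, 0.36 for antigen presentation, -0.01 for cell cycle, -0.08 for mitotic and 0.05 for mismatch repair genes, at percentiles 8.56, 83.9, 31.03, 17.5 and 50.6.

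CDX2, the transcription factor of intestinal differentiation, ranged from -3.50 in LOVO to 3.27 in SK-CO-1 in set A and from -1.34 in COLO205 to 1.18 in COLO320 in set B. limma called 0 genes that vary with CDX2 in set A and 0 in set B. At an unadjusted p under 0.05 there were 1443 and 531 genes, where a share of 0.05 of all genes would pass by chance alone. Robust empirical Bayes called 0 and 0. Quantile normalization called 1 gene in set B, as did counting each line on its own. The 13 other absorptive enterocyte genes had median slopes of 0.16 and 0.08 on CDX2, and camera adjusted p of 0.743 and 0.882. The 17 epithelial genes had median slopes of 0.40 and -0.15, with camera adjusted p of 2.57e-08 and 0.485, and the adjusted p was 0.353 and 0.983 with an estimated correlation. The haematopoietic, hepatocyte, melanocyte and mesenchymal lists also passed camera at the preset correlation in set A, with adjusted p of 0.0347, 0.0141, 0.0141 and 0.0212. With an estimated correlation these adjusted p were 0.552, 0.552, 0.144 and 0.552, and no list passed in set B. CDX2 was measured by probes that did not all vary alike.

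VIM marks the mesenchymal state and was high in few lines. It stood at -1.15 in SW-480 and SW620 in set A, where the other lines lay at or below -4.21, and at 0.17 in COLO741 and -0.63 in COLO320 in set B, where the others lay at or below -3.49. HCT116, the line measured in both sets, stood at -6.64 in set A and -3.49 in set B. It lay below the mean of -5.93 in set A and above that of -4.19 in set B. Its VIM level thus did not repeat between the sets, and no other line was measured in both. In set B limma called 129 genes that vary with VIM, 25 upward and 104 downward. In set A it called 0 genes, with 506 at an unadjusted p under 0.05. A share of 0.05 of all genes would pass that limit by chance alone, so the 506 are no sign of genes that vary. Of the 129 genes 10 were supported in set A. Among 100 orders of the VIM values the real one alone reached 10 supported genes, with 2 in the highest other. This is the smallest share such a test can give. IGSF10 and the methionine sulfoxide reductase gene MSRB3 rose with VIM, with slopes in set B of 0.70 ± 0.11 (SE, n = 13) and 0.59 ± 0.12 and in set A of 0.40 ± 0.17 (n = 14) and 0.49 ± 0.16 (n = 15). RAB25 (-0.76 ± 0.13), the epithelial transcription factor gene GRHL2 (-0.88 ± 0.15), the chloride cotransporter gene SLC12A2 (-0.66 ± 0.13) and SERPINB5 (-0.68 ± 0.15) fell with VIM in set B, with set A slopes of -0.69, -0.48, -0.52 and -1.08. TMC5, SH3RF2, CRYBG1 and SLC44A4 fell too, with set B slopes between -0.67 and -0.61.

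These calls rested on few lines. Without COLO741 and COLO320 limma called 6 genes in set B and 2 were supported, none of them among the 10. Without COLO741 alone the counts were 38 and 1, and without COLO320 5 genes were supported. Without SW-480 and SW620 the support of IGSF10, MSRB3, RAB25, GRHL2 and SH3RF2 in set A ended. The supported genes were 6 without SW948, 16 without SK-CO-1 and 17 without HCT116. The counts also rose with other processing, to 298 called and 44 supported when arrays were scaled by their median absolute deviation and to 224 and 41 with quantile normalization. With imaging batch as a block 27 genes were supported, and 21 with each line on its own. As lists, in set B the epithelial genes fell with VIM, with a median slope of -0.61 and a camera adjusted p of 6.01e-27, and the melanocyte genes rose, with 0.42 and 2.98e-11. With an estimated correlation the adjusted p was 0.0117 for both. Of the lines of set B, COLO741 had the highest VIM and a melanocyte list at 4.27 above the others, with COLO320 next at 0.48. Without COLO741, an alternative chosen after seeing the data, the median slopes were -0.44 for the epithelial and 0.07 for the melanocyte list, with adjusted p of 0.0841 and 0.182 with an estimated correlation. Without COLO741 and COLO320 they were 0.08 and 0.20, with adjusted p of 0.968 and 0.968. Without COLO320 alone both lists still passed, with median slopes of -0.64 and 0.66 and adjusted p of 0.0172 and 0.0097. Adjusted over the list alone, 17 of 17 epithelial and 9 of 11 melanocyte genes passed in set B and 0 of either in set A, where their median slopes were -0.04 and 0.03. With all lines, no other list held in set B with an estimated correlation, and in set A none did. Without COLO320 alone the Wnt targets passed too in set B, with a median slope of -0.17 and a camera adjusted p of 0.0453 with an estimated correlation. At the preset correlation the absorptive and interferon lists fell with VIM in set B, with median slopes of -0.44 and -0.37, and with an estimated correlation their adjusted p were 0.0628 and 0.118.

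Of 17 gene pairs 11 could be tested over lines, and 5 had an adjusted permutation p under 0.05. HCT116 entered once from each set, so the 28 values of a pair measured in every line came from 27 donors, and the same 5 pairs passed without either of its values. The partner keratins KRT8 and KRT18 moved together. RKO stood apart, and within the other 27 values r was 0.892 (permutation p = 1e-05) and rho 0.868 (p = 1e-05), with r of 0.842 in batch 2, 0.964 in batch 3 and 0.883 without COLO741 and SK-CO-1. The p53 targets CDKN1A and MDM2 had r of 0.560 (permutation p = 0.00286) and rho of 0.558 (p = 0.00471) within the 27 values other than that of LIM1215. Batches 2 and 3 gave 0.582 and 0.543, and r was 0.469 without HCT 116 and the LS-180 pair. Over all lines the adjusted permutation p of these pairs were 0.00011 and 0.00469. The mitotic genes TOP2A and CCNB2 had r of 0.555 (p = 0.00271, adjusted 0.00745) and rho of 0.424 (p = 0.0298, adjusted 0.0731, n = 28), with 0.636 and 0.588 in the batches and 0.405 without COLO205 and SW-837. Without COLO205 alone r was 0.44 and no longer passed. The class I genes B2M and TAP1 had r of 0.480 (p = 0.011, adjusted 0.0241) and rho of 0.498 (p = 0.00968, adjusted 0.0355), with 0.609 and 0.571 in the batches and 0.548 without LOVO and the GP2D pair.

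For CDH1 and VIM the adjusted permutation p over all 28 values was 0.00469, but SW-480 with SW620, COLO741 and COLO320 formed a cluster of their own. Within the other 25 values r was -0.208 (permutation p = 0.389) and rho 0.0104 (p = 0.967), and r was 0.152 without HCT116 and RKO as well, so the relation rested on those lines. CDX2 had r of 0.219 with CDH17 and 0.081 with VIL1, with adjusted permutation p of 0.422 and 0.666. AXIN2 and LEF1 (0.151, adjusted 0.539), FGA and FGB (0.277, adjusted 0.33) and MUC2 and TFF3 in set B (0.038, adjusted 0.9) did not pass either. Their rho values were 0.409, 0.187, 0.265, 0.390 and -0.088, with adjusted p of 0.0731, 0.4, 0.244, 0.0758 and 0.778. CDX1 and KRT20 were measured together in set B alone and fell into clusters, with r of 0.107 (permutation p = 0.805) and rho of 0.238 (p = 0.58) over the larger cluster of 8. Without LIM2412 and LS411 r in that cluster was 0.761, so its value rests on those lines. Over all 13 values the adjusted permutation p was 0.0700. Batches 1 and 4 held too few lines for a value, with 5 and 1.

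Single genes differed widely between lines. The galectin LGALS4 had the largest SD by the mean of the 2 sets, 4.21 (n = 15) and 3.94 (n = 13), from -6.39 in HCT116 to 5.07 in LS-180 with LS-174T in set A. The glutathione peroxidase GPX2 followed by that mean, with 4.77 and 3.28, and then the mucin glycosyltransferase GCNT3 (4.24 and 2.72), TSPAN8 (4.09 and 2.86), the intestinal cadherin CDH17 (3.72 and 3.05) and the mucin MUC13 (3.42 and 3.06). Signalling genes were among the 25 as well, with the EGF receptor ligand EREG (3.13 and 3.31), the Wnt antagonist DKK1 (3.13 and 2.76) and the exchange factor VAV3 (3.28 and 3.14). AGR2, KLK6, TCIM, CD200, EHF, SPINK1, ALDH1A1, CYP24A1, IFI27, FABP1, PPP1R1B, MMP7, PLA2G2A, PRR15L, PLAC8 and COXFA4L3 completed them. RKO was the lowest line of set A for GPX2 (-9.70), GCNT3 (-8.32), TSPAN8 (-6.07), CDH17 (-5.24), MUC13 (-6.90) and EREG (-6.80), and COLO741 the lowest of set B for LGALS4 (-5.53), TSPAN8 (-3.61), CDH17 (-3.41), MUC13 (-5.05) and EREG (-5.03). The median SD over 11704 genes was 0.83 and 0.69, 145 genes had a mean SD over 2, and the rank correlation of the SD between sets was 0.517 across genes, which are not independent. By median absolute deviation 13 of the 25 genes remained.

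Members of 10 lists moved together over lines in both sets, with a one-sided permutation test against matched random lists. The mean correlation was 0.610 in set A and 0.714 in set B for epithelial genes, 0.488 and 0.609 for cell cycle genes, 0.502 and 0.566 for mitotic genes and 0.431 and 0.653 for interferon response genes, each at the smallest permutation p of 1e-04. Antigen presentation (0.304 and 0.286), absorptive (0.239 and 0.315), mesenchymal (0.217 and 0.302), secretory (0.224 and 0.166), haematopoietic (0.141 and 0.180) and p53 target genes (0.118 and 0.173) had adjusted permutation p between 0.000229 and 0.0253. Hepatocyte genes passed in set A alone (0.333 and 0.0546), and melanocyte (0.0575 and 0.505), mismatch repair (0.0877 and 0.177) and Wnt target genes (0.105 and 0.102) in set B alone, and the difference between the sets was not tested. Without COLO741 and COLO320 the mean correlation of epithelial genes in set B was 0.180, with an adjusted permutation p of 0.0176. Melanocyte genes then had 0.116, Wnt targets 0.0499 and p53 targets 0.0723 in set B, with adjusted permutation p of 0.148, 0.196 and 0.196. Neuroendocrine genes (-0.0482 and -0.00767) and coding microsatellite mutation targets (0.0627 and 0.00367) passed in neither.

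**Figure D3:**
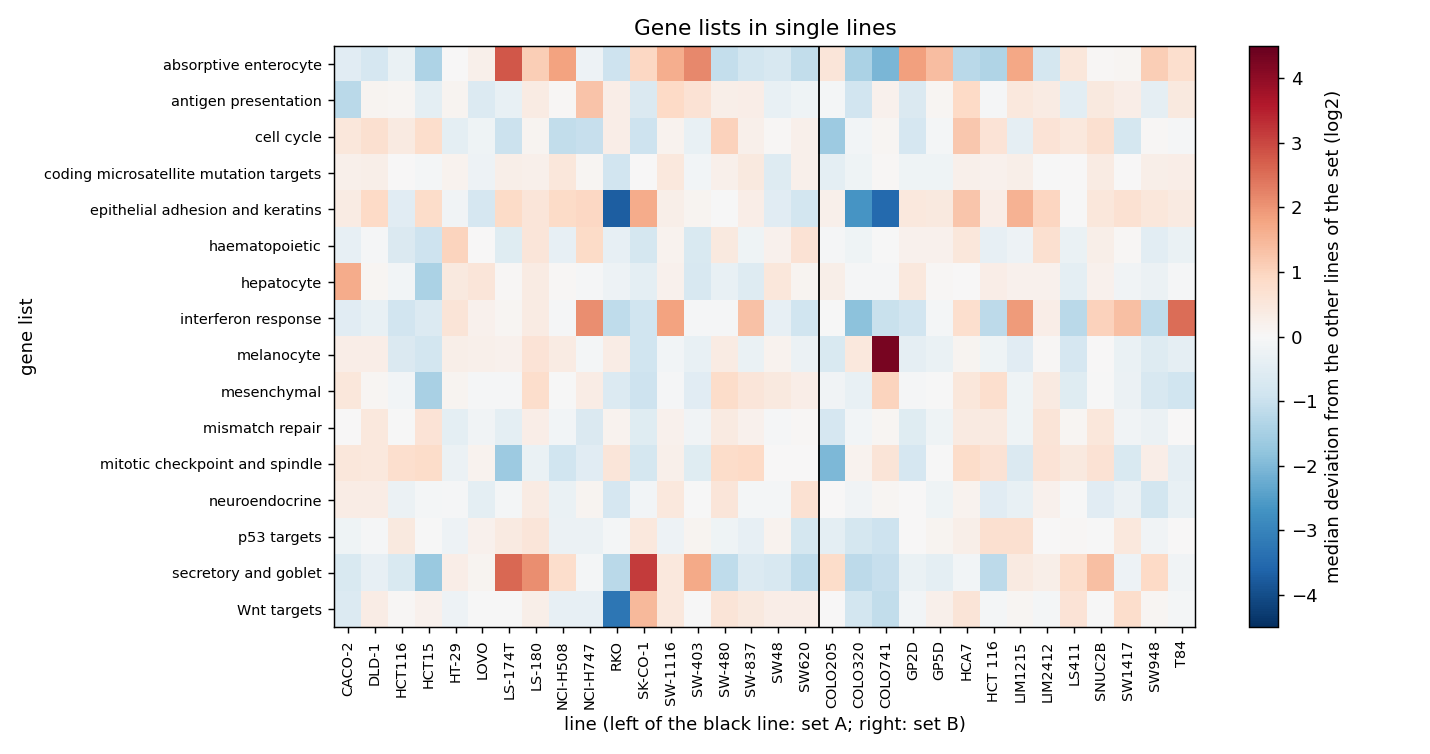
Median log2 deviation of the members of each of the 16 gene lists in each line from the mean of the other lines of its set, on a colour scale from blue (lower) to red (higher). The melanocyte list is highest in COLO741, at 4.27, and the epithelial list is lowest in RKO, at -3.72.

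Of the 4 pairs of sister lines, LS-180 with LS-174T, DLD-1 with HCT15 and SW-480 with SW620 were each other's nearest arrays. After centring each gene over the arrays of a set, LS-180 and LS-174T had r of 0.773 across genes, DLD-1 and HCT15 0.346 and SW-480 and SW620 0.194. Genes are not independent replicates, so these are values without a test. HCT 116 had r of 0.573 with HCT116+Ch3 and 0.565 with HCT116+Ch2, and the derivatives 0.546 with each other. COLO741 and COLO320 were nearest to each other at 0.335. GP2D and GP5D were not nearest to each other, at 0.107, with COLO205 and LIM1215 nearest to them. On the 2000 genes of largest SD their r was 0.288, and there GP2D and GP5D were each other's nearest arrays. The median over all pairs was -0.067 in set A and -0.099 in set B. HCT116 of set A was the line nearest to HCT 116 of set B, with r of 0.298 across genes, ahead of HCT15 with 0.148.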

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

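The deposited array median as a covariate, leaving out the second run of images, leaving out 4 lines and removing the image-run mean were chosen only after the results were seen, and the other alternatives before. Of the counts reported, 84 values under the alternatives lay within 1.5 times the main value and 17 did not, and with single lines left out 242 did and 10 did not. Of the values of named genes and pairs, 961 kept their direction and side of the threshold, 66 fell below it, 18 rose above it and 8 changed sign. With single lines left out these numbers were 2701, 86, 10 and 3. Of the gene differences in the HCT116 derivatives 112 kept within the spread and 31 moved beyond it. The causes below were not tested unless named. On the deposited scale, which lowers every gene, 286 genes were higher than the reference and 4678 lower, and CCNB2 turned to -0.063. Probes on every array, with fewer genes tested, gave 886 lower genes, an r of -0.000225 for CDX2 and CDH17 and one of -0.0162 for CDX2 and VIL1. Without the second run of images, with fewer lines, 991 genes were higher. The most complete probe turned CIITA to 0.21 and FGA and FGB to an r of -0.178, and lowered the chromosome 2 median in HCT116+Ch2 to 0.094. Imaging batch as a block turned CDX2 and VIL1 to -0.208 and MUC2 and TFF3 to -0.158. CDX2 called 1 gene in set B with quantile normalization and 1 with each line on its own. For VIM, scaling arrays by their median absolute deviation gave 298 genes in set B and 44 supported, quantile normalization 224 and 41, leaving out COLO741 and COLO320 6 and 2, and leaving out SW-480 and SW620 as well 6 and 1. The supported genes were 27 with imaging batch as a block and 21 with each line on its own. Without those 4 lines the VIM slope of GRHL2 turned to 0.040. With the other derivative as the control the chromosome 3 median in HCT116+Ch3 was 0.36. By median absolute deviation 13 of the 25 most variable genes remained. GP2D and GP5D had r of 0.288 on the 2000 genes of largest SD and 0.319 with the image-run mean removed. With each line left out in turn, 1611 to 1885 genes were higher and 2021 to 2198 lower, 4 to 6 pairs passed, CDX2 called 0 to 2 genes in set A and 0 to 1 in set B, and VIM called 38 to 160 genes in set B with 1 to 17 supported. CDX2 reached 2 without SW-403 or HT-29, and 1 without COLO320 or HCA7. The r of MUC2 and TFF3 reached 0.238 without LIM1215 and turned to -0.184 without COLO205, -0.158 without HCT 116 and -0.0240 without SW948. No paired analysis was possible because the groups share no replicate that pairs them, with 1 array for each derivative. The alternatives for the planned mismatch repair covariate were not run. Signal over background is unknown here, so weak spots could not be told from strong ones.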

Other observations

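Relations between lists over lines and their values with HCT116 counted once, the image runs, the melanocytic genes outside the fixed list, the test of a minority of melanocytic cells and the orders of the VIM values, with all lines and without COLO741 or COLO320, were chosen only after related results were seen. Single lines stood apart in whole gene lists, given as the median log2 deviation of a list from the other lines of the set. RKO had the lowest Wnt target list, at -3.24, and COLO320 had low epithelial genes, at -2.67, and low interferon response genes, at -1.84. Interferon response genes were high in T84 (2.52), NCI-H747 (2.10), LIM1215 (1.92) and SW-1116 (1.79). SK-CO-1 had high secretory and goblet genes (3.14), as did LS-174T (2.60) and LS-180 (2.11), and LS-174T and SW-403 had high absorptive enterocyte genes (2.79 and 2.16). CACO-2 had high hepatocyte genes (1.66) and low antigen presentation (-1.22), secretory (-0.67) and absorptive genes (-0.51). COLO205 had low mitotic (-2.03) and cell cycle genes (-1.65), and HCA7 had high cell cycle genes (1.22). Each of these lines had 1 array, so these are values with no replicate check.

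Of 120 relations between lists over the 28 values, with HCT116 counted once in each set, 17 had an adjusted permutation p under 0.05, and in 5 of these the lines formed no clusters. The cell cycle and mismatch repair lists rose together, with r of 0.843 (adjusted permutation p = 0.0004) and rho of 0.790 (adjusted 0.0003), r of 0.793 in batch 2 and 0.885 in batch 3, and 0.787 without COLO205 and HCA7. The mismatch repair list includes the clamp loader genes RFC1, RFC3, RFC4 and RFC5 and the polymerase POLD1. Its relation with the cell cycle list was not tested without them. Absorptive and secretory genes had r of 0.735 (adjusted permutation p = 0.0006) and rho of 0.771 (adjusted 0.0003), with 0.823 and 0.514 in the batches and 0.731 without LIM1215 and SW-403. Antigen presentation and interferon response genes had r of 0.684 (adjusted permutation p = 0.0014) and rho of 0.610 (adjusted 0.0161), with 0.786 and 0.777 in the batches and 0.672 without CACO-2 and NCI-H747. Absorptive and cell cycle genes moved oppositely, with r of -0.510 (adjusted permutation p = 0.0479) and rho of -0.606 (adjusted 0.0161), -0.596 and -0.372 in the batches and -0.502 without LIM1215 and SW-403. With HCT116 counted once this relation no longer passed, with adjusted permutation p of 0.0545 without its value in set A and 0.0653 without that in set B, and the other 4 passed either way. Haematopoietic and mesenchymal genes had r of 0.501 (adjusted permutation p = 0.0419) and rho of 0.593 (adjusted 0.02), 0.676 and 0.674 in the batches and 0.564 without HT-29 and NCI-H747, but an adjusted permutation p of 0.0652 with the image runs as a block.

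Chromosome 3 genes were higher in HCT116+Ch3 in 4 of 5 blocks. The lowest block, from CACNA2D3 to WDR5B, had a median of 0.051, at the 52.3rd percentile of random lists. It was mixed, since in 20 blocks its ends were raised, at 0.45 from CACNA2D3 to TAFA1 and 0.26 from ATP6V1A to WDR5B. Its middle stood at -0.05 from TAFA4 to TOMM70 and -0.14 from LNP1 to NAA50. A candidate explanation is a gain of part of chromosome 3 that leaves out this middle. An array trend shared with other arrays was tested by regressing out their leading gene pattern, after which chromosome 3 stood at 0.32 and the next chromosome, 19, at 0.21. By the criterion written beforehand that result counts against the trend, but the reading was changed to undecided once it was seen, because the pattern had r of only -0.0746 across genes with the difference and its removal moved almost nothing. A shared trend therefore stays open, the raised medians of chromosomes 19 and 22 and the lowered ones of 4 and 13 are unexplained, and 1 array cannot tell the line from the array. Against HCT116+Ch2 the medians of chromosomes 19, 22, 4 and 13 were 0.26, 0.20, -0.07 and -0.04. They lay at percentiles 100, 99.78, 0 and 1.125 of random lists, so they do not rest on the HCT 116 array alone.

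The 13 arrays of batch 3 fell into runs of 8 and 5 images, by the image numbers in the labels, with deposited medians of -0.32 to -0.22 and -0.91 to -0.77. limma called 1538 genes between the runs, and 1 of 100 splits of the arrays, the real one, called as many, with 5 in the highest other. No other split came near that count, but 1 of 100 is the smallest share this test can give. Over 9202 genes the run difference had r of 0.284 with the slope on the deposited median in set A, against -0.194 to 0.193 for shuffled medians, so an array effect that goes with the deposited median may contribute. With the mean of each run removed GP2D and GP5D became nearest to each other, with r of 0.319, and the image runs are a candidate cause of their distance. They were also nearest to each other on the 2000 genes of largest SD with no run mean removed, at 0.288. Becoming nearest therefore does not single out the runs. The runs hold different lines, so part of the difference may still be biological, which was not tested.

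COLO741 had the melanocyte list at 4.27 above the other lines, with log2 ratios of 4.84 for MITF, 4.77 for TYRP1, 3.44 for RAB38, 2.39 for PMEL and 1.97 for SOX10. Melanocytic genes outside that list, 16 of 19 measured, had a median deviation of 2.95, above all random lists, led by GPNMB (7.37) and CAPN3 (5.16), and the next line, LIM1215, had 0.28. The epithelial list lay at -3.48, which argues against a minority of melanocytic cells in an epithelial culture. A culture made up of melanocytic cells remains a hypothesis, and a mislabelled array or a mixed-up line stays open.

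The 129 genes called with VIM in set B were reached by 1 of 100 orders of the VIM values, the real one, with 94 genes in the highest other order. Such a count was thus rare among orders, but 1 of 100 is the smallest share this test can give. High VIM values lay in COLO741 and COLO320 alone, so an order mainly sets which lines receive them. Chance is therefore not excluded. The 38 genes left without COLO741 were reached by 3 of 100 orders, the real one included, and 1 order called 64. Without COLO320 the 110 genes were reached by the real order alone of 100, with 84 in the highest other. Without COLO741 and COLO320 the 6 genes were again reached by 3, with 13 in the highest other order. In set A, where the real order called 0 genes, the highest other order called 62 and the median order 0. A single order can thus call many genes without the real VIM values, and the reason was not tested.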
